A study of Mus musculus with 11 samples.

How the data were processed

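Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on CD4 T cells from mouse lymph nodes and spleen. Per the labels' protocols, the cells were sorted by a green fluorescent protein reporter of Foxp3, fixed with formaldehyde and sonicated. The 11 samples fell into 8 groups by their labels. Foxp3-positive regulatory T (Treg) cells gave 3 Foxp3 libraries (replicate 1 as 2 technical replicates, and replicate 2), 2 input libraries, and 1 library each for Elf1, Ets1 and Cbfb. Foxp3-negative CD4 T cells, called CD4 below, gave 1 library each for Elf1, Ets1 and Cbfb. The CD4 Cbfb library, which its label calls low in quality, and the input libraries were not analysed here.

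Reads had been aligned with Bowtie 0.12.7 to mouse build mm9, per the submitters' processing notes. For Foxp3, the authors deposited 1 list of 2886 intervals from their combined replicates, per the labels, with a start and an end and no score. Each interval was 200 bp wide. For each of the other 5 libraries the authors deposited a list of single-base binding positions with, per the file headers, a score, an E-value, a false discovery rate (FDR, a q-value), and a fold enrichment as its lower bound and its maximum likelihood estimate. The column names were those that the SPP package writes, but the caller, the thresholds and the control behind the fold enrichment were not given in the sources used here. The number of reads per library was also unknown, so list lengths and scores could not be set against depth. Scores and fold values are the authors', per position, and mainly rank or filter positions within a list. Coordinates are given as in the files, in mm9.

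Before the data were examined, positions with an FDR of at most 0.01 were chosen as the main lists. A Foxp3 peak was counted as shared when a position lay within 200 bp of its interval, and 2 positions were counted as common when they lay within 200 bp of each other. Because the lists that passed differed in length, the 10000 and the 20000 positions with the highest score in each library were used beside them. As background, the Foxp3 peaks, or the positions of the first list, were moved around each chromosome 1000 times by a random distance with a fixed seed. Chromosome lengths were those of mm9; for unplaced contigs the highest coordinate in any list was used. A second background moved each Foxp3 peak by 10 kb up and down, which keeps it in the same neighbourhood. Shares have exact Clopper-Pearson 95% intervals, and counts per length exact Poisson 95% intervals. Both cover counting error only.

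Each analysed group other than Foxp3 had 1 library, so differences had no replicate check and no p-values are given. Where positions at Foxp3 peaks were compared with others, random lists of the same size were drawn from positions away from Foxp3 peaks, with replacement, and the observed value is given with its percentile among them. For the Treg minus CD4 log2 ratio of fold enrichment, 10000 lists were matched in 20 bins of mean log2 fold enrichment. For co-occupancy, 1000 lists were matched in 20 bins of score, with the bin limits set on the positions at Foxp3 peaks. Leaving the Foxp3 positions out of the pool and drawing with replacement were choices made during the analysis. These percentiles describe these libraries only. The functions were tested on simulated data made from the real lists. Shares of 2886 simulated peaks were recovered within 0.444 percentage points. A planted log2 ratio of 0.2 came back as 0.20 for both factors, and with no ratio planted the method returned 0.038 for Elf1 and 0.040 for Ets1. Each value came from a single simulated run, so they give no range for the method's own error.

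The rule for named positions, set before the data were examined, took the 10 Foxp3 peaks with the highest score or width, which could not be applied because the list had no score and 1 width. It also took, for Elf1 and Ets1 in each cell type, the 3 highest scores at Foxp3 peaks with no position of any score within 1 kb in the other cell type, and the 3 highest Cbfb scores at Foxp3 peaks. The gap of 10 kb that defined clusters of Foxp3 peaks, the 4-fold limit for weak enrichment and the region on chromosome X were chosen after the data had been seen. The only gene table used here is on another build, so positions carry no gene names. Counts of peaks at gene lists and searches for sequence motifs, both planned, were not run. Alternatives were a stricter FDR, all deposited positions, lists of equal length, distances of 100 and 500 bp, peak midpoints, another background, another centring and the exchange of score and fold enrichment. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.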

Results

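Binding of Foxp3, the transcription factor that defines regulatory T cells, was mapped in Foxp3-positive Treg cells of the mouse. Elf1 and Ets1, members of the ETS family, were mapped in Treg cells and in Foxp3-negative CD4 T cells, and Cbfb, the non-DNA-binding partner of Runx proteins, in Treg cells. The Foxp3 list, pooled by the authors from their replicates, held 2886 peaks. At an FDR of at most 0.01 the lists held 157731 positions for Treg Elf1, 61761 for Treg Ets1, 121632 for Treg Cbfb, 53580 for CD4 Elf1 and 42040 for CD4 Ets1. Their median fold enrichment ran from 3.71 for Treg Ets1 to 5.71 for Treg Elf1. Each of these lists came from 1 library, and the depth of the libraries is unknown, so intervals below cover counting error only.

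Foxp3 peaks were unevenly spread over the genome. Chromosome 11 carried 20.4 peaks per 10 Mb (95% interval 17.9 to 23.1), against 11.6 per 10 Mb (11.2 to 12) over all numbered chromosomes. Chromosome X carried only 22 peaks, or 1.32 per 10 Mb (0.827 to 2.00). The 10000 highest Elf1 and Ets1 positions were also sparse on X, at 13.1 and 17.1 per 10 Mb in Treg and 9.36 and 8.52 in CD4, while the Treg Cbfb list held 37.4 per 10 Mb there. On chromosome 11 the same Elf1 and Ets1 lists held between 64.3 and 79.0 positions per 10 Mb, and Cbfb 42.7. The Cbfb list was more even over the numbered chromosomes, from 27.0 on chromosome 7 to 44.5 on chromosome 3, and its value on X lay inside that range.

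Foxp3 peaks also lay in clusters. With neighbours at most 10 kb apart, 1113 peaks (38.6%) fell into 457 clusters of 2 or more. When the same number of peaks per chromosome was placed at random 100 times, 2.36% ± 0.41 (SD over placements) did so. These placements were uniform over each chromosome, so any factor with preferred regions would exceed them. Clustering in the other lists was not measured, so the contrast shows nothing particular to Foxp3. The cluster with the most peaks held 8, on chromosome 6 between 48668562 and 48696202, and the next held 7, on chromosome 9 between 32295128 and 32326226. These 2 clusters were named after the counts had been seen.

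The first comparison asked whether Foxp3 sat where other factors bound in the same cell type. Of the 2886 Foxp3 peaks, 85.2% (83.9 to 86.5) had a Treg Elf1 position, 83.5% (82.1 to 84.8) a Treg Ets1 position and 28.1% (26.5 to 29.8) a Treg Cbfb position within 200 bp. At least 1 of the 3 factors was present at 2776 peaks (96.2%). At 1614 peaks 2 of them were present, and at 646 all 3. Elf1 positions lay at a median of 55 bp, Ets1 positions at 63 bp and Cbfb positions at 60 bp from the centre of the Foxp3 peak. After Foxp3 peaks were moved by 10 kb, the median distance of those that still had a position was 149, 137 and 138 bp.

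Circular shifts of the Foxp3 peaks gave a mean of 3.51% for Treg Elf1, with a highest value of 4.54% in 1000 shifts. The mean was 1.41% (highest 2.36%) for Ets1 and 2.73% (highest 3.85%) for Cbfb. Peaks moved by 10 kb gave 8.19, 6.20 and 4.49%. With the 10000 highest positions of each library, the Foxp3 shares were 54.4% for Treg Elf1, 61.0% for Treg Ets1 and 11.1% for Treg Cbfb, so at one list length Cbfb covered the fewest Foxp3 peaks and Ets1 the most of these 3. The Treg Cbfb library was weakly enriched at many of its high scores: 48 of its top 200 positions were under 4-fold, against 0 to 3 in the other libraries. Its median fold over the 10000 highest positions, 5.75, was near the 5.99 of Treg Ets1.

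The second comparison asked whether the sites that Foxp3 occupied were already bound by Elf1 or Ets1 in T cells without Foxp3. In CD4 cells 88.9% of Foxp3 peaks (87.7 to 90.0) had an Elf1 position and 89.0% (87.8 to 90.1) an Ets1 position. Either was present at 2751 peaks, 95.3% (94.5 to 96.1). CD4 Elf1 and Ets1 positions lay at a median of 44 and 45 bp from the Foxp3 peak centre. Circular shifts gave means of 1.26% for Elf1, 0.985% for Ets1 and 1.89% for either. For either factor the highest value in 1000 shifts was 3.05%, and peaks moved by 10 kb gave 9.36%.

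Most Foxp3 peaks had Elf1 or Ets1 in both cell types. The number was 2655 of 2886 (92.0%, 90.9 to 93.0). A further 101 peaks had a position only in Treg, 96 only in CD4 and 34 in neither. For Elf1 alone, 161 Foxp3 peaks had a position only in Treg and 266 only in CD4, and for Ets1 alone the numbers were 199 and 357. All 4 Elf1 and Ets1 lists had a position at 1908 peaks. Only 31 peaks lacked a position of any of the 5 libraries, and 7 did so when all deposited positions were used. With the 10000 highest positions of each library, 1999 peaks (69.3%) had Elf1 or Ets1 in both cell types. Elf1 was then found only in Treg at 268 peaks (9.29%) and only in CD4 at 406 (14.1%). For Ets1 the numbers at this list length were 317 (11.0%) and 604 (20.9%).

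**Figure D1:**
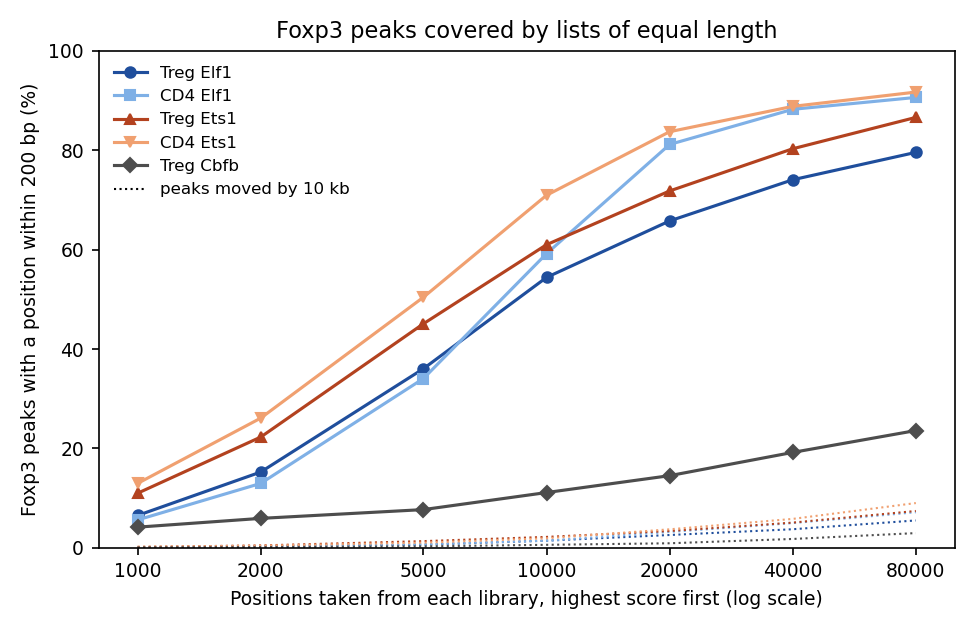
Share of the 2886 Foxp3 peaks (vertical axis, percent) with a position within 200 bp, against the number of highest-scoring positions taken from each library (horizontal axis, log scale); solid lines and symbols show the 5 libraries and dotted lines the same peaks moved by 10 kb. At 20000 positions the shares were 81.2% for CD4 Elf1, 83.7% for CD4 Ets1, 65.8% for Treg Elf1, 71.8% for Treg Ets1 and 14.5% for Treg Cbfb.

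With 10000 to 80000 positions per library, the CD4 lists covered more Foxp3 peaks than the Treg lists for both factors. For Ets1 the CD4 list covered, at 10000 positions, 70.9% (69.2 to 72.6), against 61.0% (59.2 to 62.8) in Treg. For Elf1 the order depended on the length: at 5000 positions the Treg list covered 36.0% and the CD4 list 34.1%, and at 10000 they covered 54.4% (52.6 to 56.2) and 59.2% (57.4 to 61.0). With 1 library per group, these differences had no replicate check.

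The third comparison set the Elf1 and Ets1 maps of the 2 cell types against each other. Of the 10000 highest Treg Elf1 positions, 63.9% (63.0 to 64.9) had a counterpart among the 10000 highest CD4 Elf1 positions, and 63.1% of the CD4 positions had one in Treg. For Ets1 both shares were lower, at 46.2%. Circular shifts gave at most 0.60% in any of these 4 cases. With all positions at an FDR of at most 0.01, 11.4% of Treg Elf1 positions had a CD4 counterpart and 32.5% of CD4 positions a Treg counterpart. The same shares for Ets1 were 18.7 and 27.7%.

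At Foxp3 peaks the fold enrichment of Ets1 was lower in the Treg library than in the CD4 library. Over 2149 Treg Ets1 positions with a CD4 counterpart at Foxp3 peaks, the median Treg minus CD4 log2 ratio was -0.52 (SD over positions 1.03). Of these positions 71.8% were lower in Treg, but so were 67.7% of the common Ets1 positions away from Foxp3 peaks. Random lists of common Ets1 positions away from Foxp3 peaks, matched on mean enrichment, gave a median of -0.42 with a central 95% from -0.47 to -0.37, and none of 10000 lists was as low. For Elf1 the median at Foxp3 peaks was -0.23 over 2360 positions, inside the matched range of -0.30 to -0.20 (percentile 86.5). The Ets1 ratio differed from the matched lists by -0.098. A single simulated run with nothing planted returned 0.040, which gives no range for the method's error. Fold values of 2 libraries with unknown depth and control are compared here, so the ratios describe the libraries and not the cell types. For Elf1 the call depended on the list. Relative to matched lists its value was -0.13 with all deposited positions, below every list, and 0.094 with the 10000 highest, above the central 95%. It was also above that range with an FDR of at most 0.001, with the 20000 highest and by score. The simulated run for Elf1 with nothing planted returned 0.038, also a positive value, and its spread over runs is not known. The Ets1 value was -0.28 with all deposited positions and -0.052 with the 10000 highest.

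In the Treg libraries, at equal list length, Elf1 and Ets1 shared far more positions with each other than either did with Cbfb. In the Treg Cbfb library 48 of the top 200 positions were under 4-fold. Over the 10000 highest positions, though, the median fold of Treg Cbfb was 5.75, against 5.99 for Treg Ets1 and 13.2 for Treg Elf1. Weak enrichment of that library and less shared binding cannot be told apart here. Among the 10000 highest positions of each library, 28.5% (27.6 to 29.4) of Treg Elf1 positions had a Treg Ets1 position within 200 bp. Cbfb was present at 3.55% (3.20 to 3.93) of Elf1 positions and at 4.39% (4.0 to 4.81) of Ets1 positions. Circular shifts gave means between 0.152 and 0.162% for these pairs. In CD4 cells 50.2% (49.2 to 51.2) of the Elf1 positions had an Ets1 position. With the FDR lists, the shares in Treg were 7.26% for Elf1 with Ets1, 4.06% for Elf1 with Cbfb and 5.88% for Ets1 with Cbfb, against shift means of 0.940, 1.86 and 1.86%.

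At Foxp3 peaks, positions of different factors lay within 200 bp of each other more often than in matched lists. The lists were matched on the score of the first factor only, so sites that recur in any library could also give such an excess. Treg Elf1 positions at Foxp3 peaks had an Ets1 position in 73.7% of cases (72.0 to 75.3), against a mean of 28.3% in lists of Elf1 positions matched on score. They had a Cbfb position in 23.6% of cases, against 7.30%. Treg Ets1 positions at Foxp3 peaks had a Cbfb position in 24.9% of cases, against 9.83%. The same held in cells without Foxp3: CD4 Elf1 positions at the places of Foxp3 peaks had an Ets1 position in 87.6% of cases, against 59.1%. None of the 1000 matched lists reached the observed share in any of these cases.

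**Figure D2:**
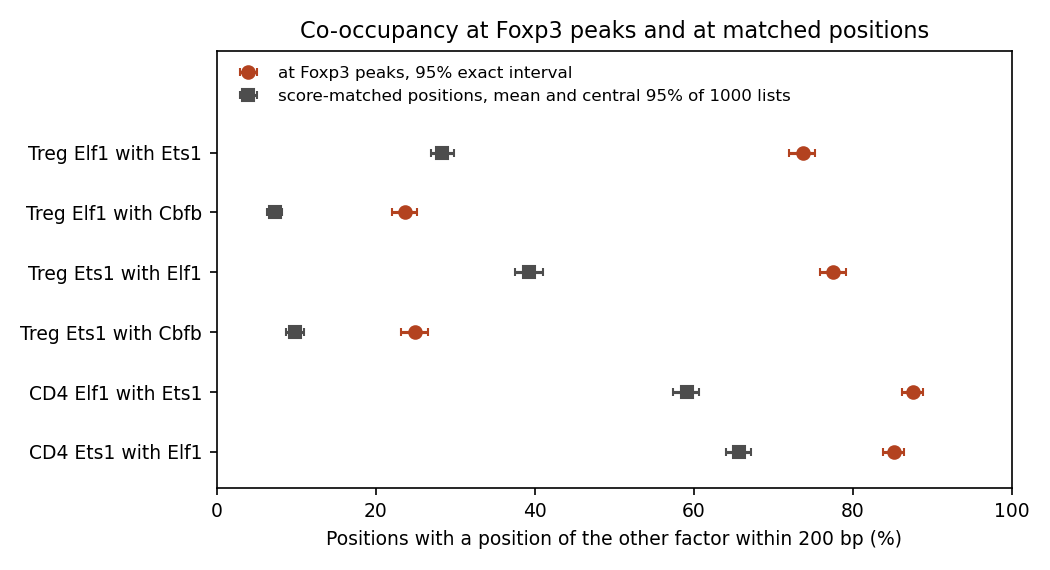
Percent of Elf1 or Ets1 positions (horizontal axis) that had a position of the second named factor within 200 bp, for 6 pairs of lists at an FDR of at most 0.01. Circles show positions at Foxp3 peaks with exact 95% intervals (counting error only), and squares the mean and central 95% of 1000 score-matched lists; for Treg Ets1 with Elf1 the values were 77.6 and 39.3%, and for CD4 Ets1 with Elf1 85.2 and 65.6%.

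Seen from either factor, joint positions lay at Foxp3 peaks more often than single ones, a comparison added after the data had been seen. Joint and single positions were not matched on score. Ets1 was present at 42.4% of Treg Elf1 ranks 1 to 500, against 28.5% of the top 10000. In CD4 these shares were 88 and 50.2%. How much of the difference came from score was not tested. Within ranks 1001 to 2000, 40.7% of Treg Elf1 positions with Ets1 lay at a Foxp3 peak, against 24.8% of all. For CD4 Elf1 the shares were 27.0 and 20%. Within CD4 Elf1 ranks 1 to 500 they were closer, at 16.8 and 15.2%. Of the 2847 Treg Elf1 positions among the top 10000 that also had a top 10000 Ets1 position, 34.6% (32.8 to 36.3) lay at a Foxp3 peak. Of the 7153 without one, 8.08% (7.46 to 8.74) did. For CD4 Elf1 positions the shares were 26.3% (25.1 to 27.5) with Ets1 and 6.43% (5.76 to 7.15) without. The gap was narrower for Ets1 positions with and without Elf1, at 34.7% (32.9 to 36.5) and 10.8% (10.1 to 11.6) in Treg and 26.3% (25.1 to 27.5) and 13.9% (12.9 to 14.9) in CD4.

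Foxp3 peaks lay mainly at positions with high scores. In Treg Elf1, 11.6% of the highest 10% of positions by score lay at a Foxp3 peak, against 2.37% of the next 10% and 0.311% of the lowest. For Treg Ets1 the highest and lowest 10% had 22.9 and 0.518%, for CD4 Elf1 18.5 and 0.317%, for CD4 Ets1 29.3 and 0.737%, and for Treg Cbfb 2.68 and 0.271%. The very highest scores were not the richest in every library. Among Treg Elf1 positions, 14.6% (11.6 to 18) of ranks 1 to 500 lay at a Foxp3 peak, and 24.8% (22.2 to 27.6) of ranks 1001 to 2000. In CD4 Ets1 the shares were 30% (26.0 to 34.2) for ranks 1 to 500 and 40.4% (36.1 to 44.8) for ranks 501 to 1000. Cbfb fell from its first ranks on, from 13.8% (10.9 to 17.1) to 4.40% (3.21 to 5.86) at ranks 1001 to 2000. Ranked by fold enrichment in place of score, the highest 10% had 3.74% for Treg Elf1, 6.01% for Treg Ets1, 0.378% for Treg Cbfb, 13.1% for CD4 Elf1 and 14.6% for CD4 Ets1. By fold enrichment the highest 10% was not the richest for Treg Ets1, where the next 2 groups of 10% had 7.21 and 7.66%, and the lowest 10% of Cbfb positions had 0.469%, above its highest.

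**Figure D3:**
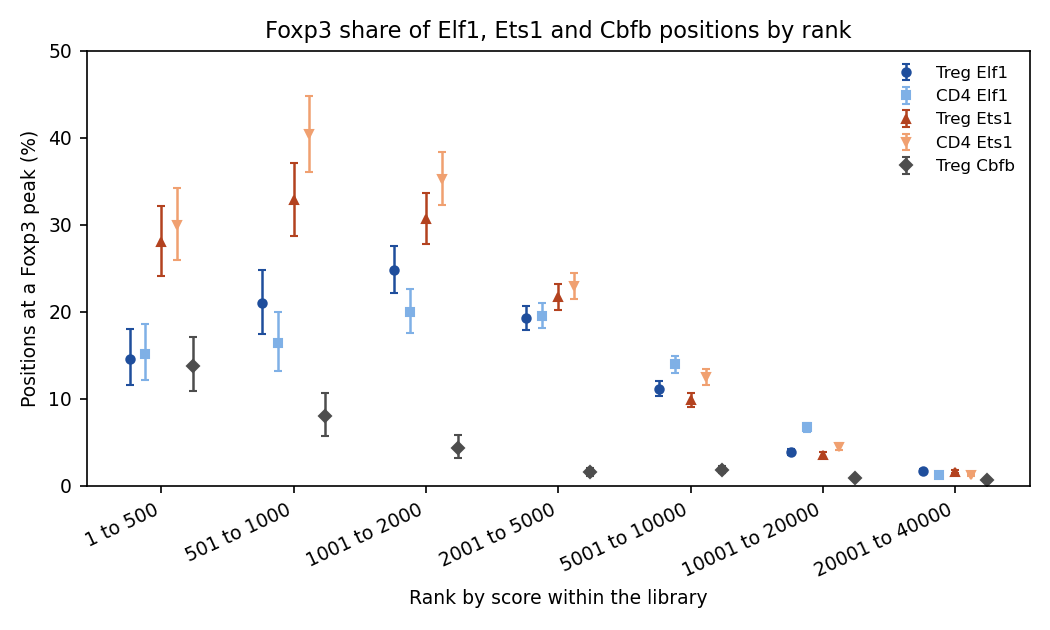
Percent of positions that lay within 200 bp of a Foxp3 peak (vertical axis) by rank of score within each of 5 libraries (horizontal axis), with exact 95% intervals that cover counting error only. Ets1 had the highest shares in the first 3 rank groups, up to 40.4% in CD4, and ranks 20001 to 40000 had at most 1.73% in any library.

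Among all deposited positions at Foxp3 peaks, few had no position of the same factor within 1 kb in the other cell type. For Elf1, 65 of 2939 Treg positions (2.21%) had none in CD4, and 167 of 2830 CD4 positions (5.90%) had none in Treg. For Ets1 the numbers were 56 of 2980 (1.88%) and 80 of 3163 (2.53%). The same shares away from Foxp3 peaks were not computed, so these values show nothing particular to Foxp3. One-sided binding was less rare with the 10000 highest positions and 200 bp. Elf1 was then only in Treg at 9.29% of Foxp3 peaks and only in CD4 at 14.1%. For Ets1 these shares were 11.0 and 20.9%. By score, the highest Elf1 position present only in Treg lay on chromosome 4 at 11011888, with a fold enrichment of 25.9 (lower bound 9.02). A Treg Ets1 position at 11011958, 70 bp away, had a fold enrichment of 6.79 and was the second of the Ets1 positions present only in Treg. The Foxp3 peak there spanned 11011958 to 11012158.

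The other Treg-only Elf1 positions lay on chromosome 17 at 73491549 (13.2-fold) and on chromosome 4 at 149932393 (31.8-fold). Both had a CD4 Ets1 position within 28 bp. The other Treg-only Ets1 positions lay on chromosome 2 at 11576967 (19.3-fold) and on chromosome 16 at 55583201 (4.39-fold). Each had a CD4 Elf1 position within 90 bp. At the site at 149932393 the CD4 Ets1 position did not pass the FDR limit of 0.01. In the other direction, Elf1 was present only in CD4 on chromosome X at 127083913 (7.40-fold), chromosome 17 at 51972598 (14.2-fold) and chromosome 8 at 108578266 (10.4-fold). All 3 had a Treg Ets1 position within 154 bp. Ets1 was present only in CD4 on chromosome 1 at 175362719 (29.5-fold) and at 167639901 (4.97-fold), and on chromosome 14 at 41772583 (3.48-fold). The first 2 had a Treg Elf1 position at 192 and 55 bp, and the third had no Treg position of any factor within 1 kb.

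The highest-scoring Cbfb positions at Foxp3 peaks lay on chromosome 11 at 106020854 (107-fold, lower bound 19.1), on chromosome 16 at 57391745 (4.51-fold) and on chromosome 11 at 32483073 (13.1-fold). All 3 had Elf1 and Ets1 positions of both cell types within 150 bp. At the first, CD4 Elf1 had a fold enrichment of 108 at the same base and Treg Elf1 of 12.2 at 28 bp, while Treg Ets1 had 93.9 at 85 bp and CD4 Ets1 20.2 at 99 bp. The control behind these values is unknown, so shared binding and low control coverage cannot be told apart at this site.

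One region, chosen after its values had been seen, held many of the most enriched Cbfb positions close together. On chromosome X between 7170208 and 7172228, a span of 2020 bp, the Treg Cbfb library had 7 deposited positions of any FDR with fold enrichments of up to 520. Of these, 5 were over 20-fold, and 4 with an FDR of at most 0.01. CD4 Elf1 had 4 positions there, all 4 over 20-fold, with up to 214-fold. Treg Elf1 reached 4.40-fold, Treg Ets1 12.6-fold and CD4 Ets1 10.9-fold, the last at an FDR of 0.193. A second stretch, 13298 bp away between 7155215 and 7156910, had 6 Cbfb positions over 20-fold, with up to 186-fold. There Treg Elf1 reached 55.3-fold, Treg Ets1 19.6-fold, CD4 Elf1 58.0-fold and CD4 Ets1 21.4-fold. The limits of both stretches were set on Cbfb positions. Just outside the second lay Treg Elf1 at 7155151 (80.7-fold) and Treg Ets1 at 7154921 (22.0-fold), and just outside the first CD4 Elf1 at 7170200 (22.2-fold). More than 20 kb away from the first stretch, no 2500 bp window held more than 2 Cbfb positions over 20-fold, but some held up to 5 CD4 Elf1 positions over that limit. The Cbfb position with the highest lower bound elsewhere lay on chromosome 1 at 60969139, at 481-fold, and there too CD4 Elf1 had a position 8 bp away (24.2-fold) while Treg Elf1 had 3.53-fold.

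**Figure D4:**
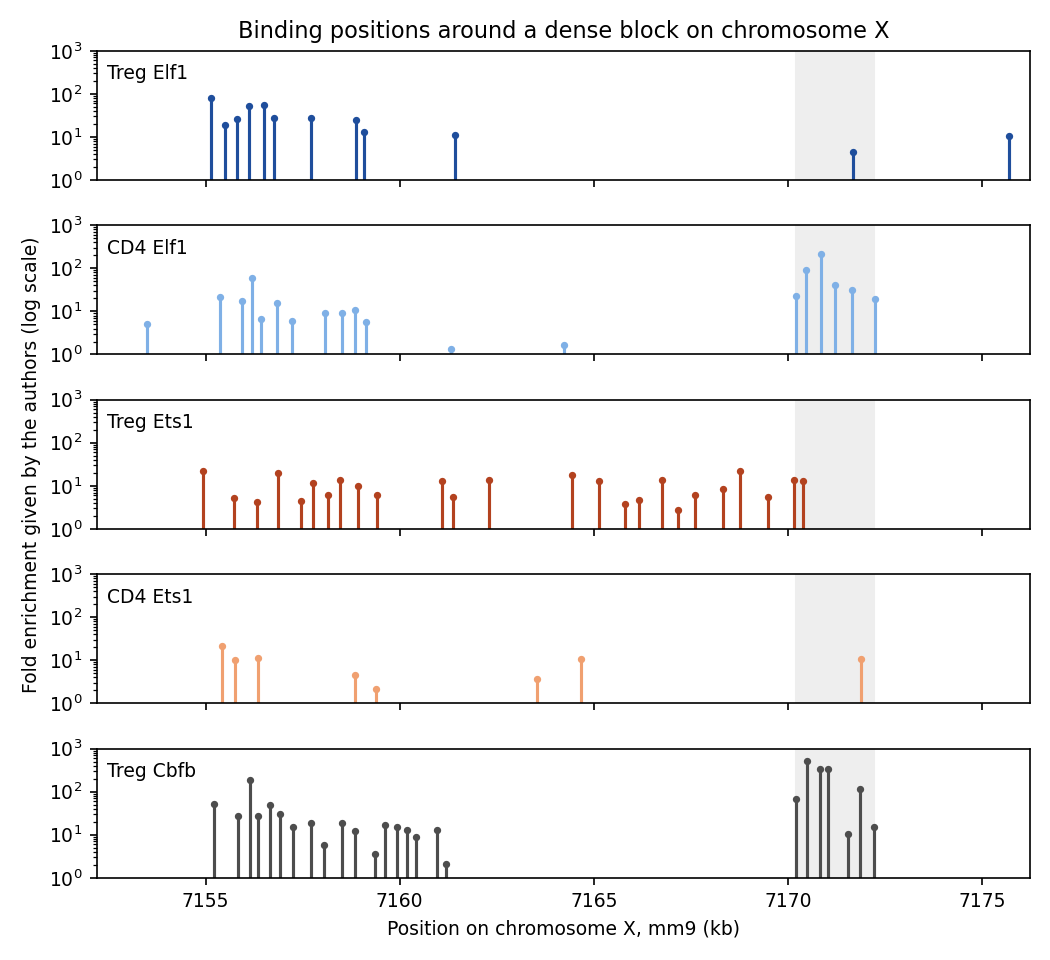
Fold enrichment given by the authors (vertical axis, log scale) of each binding position in 5 libraries along chromosome X of mm9 (horizontal axis, kb), with the dense stretch from 7170208 to 7172228 shaded. In the shaded stretch the Treg Cbfb and CD4 Elf1 libraries reached 520 and 214-fold and the other 3 libraries at most 12.6-fold.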

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

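The share of Foxp3 peaks with Treg positions without the Cbfb library, 95.5%, the Treg minus CD4 ratio started from CD4 positions and the gaps between clustered peaks were chosen after seeing the data; the other alternatives were set before. With neighbours within 5 kb 30.2% of Foxp3 peaks were clustered, and within 20 kb 46.3%, as a wider gap joins more peaks by construction. Co-occupancy at Foxp3 peaks stayed above all matched lists under each of the 6 alternatives run: the excess was 34.7 to 52.6 percentage points for Elf1 with Ets1, 7.89 to 21.2 for Elf1 with Cbfb and 8.55 to 17.5 for Ets1 with Cbfb. The Treg minus CD4 ratio of Ets1 relative to matched positions stayed negative in all 10 alternatives, from -0.28 to -0.052. For Elf1 it turned to -0.13, below all matched lists, with all deposited positions, and moved above the central range with an FDR of at most 0.001 (0.060), the 10000 highest (0.094), the 20000 highest (0.061) and score in place of fold (0.060). A simulated run with nothing planted had returned 0.038 for Elf1, a positive value too. The Elf1 ratio also changed sign, to -0.052, when centred on all common positions without a Foxp3 peak, which has no matched range. The cause of these changes was not tested.

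The other shares moved beyond their counting intervals under nearly every alternative. They are given below in one order: Foxp3 peaks with Treg Elf1, Treg Ets1, Treg Cbfb, CD4 Elf1, CD4 Ets1, any Treg factor and either CD4 factor; then Treg positions common to CD4 for Elf1 and Ets1; then Elf1 with Ets1, Elf1 with Cbfb and Ets1 with Cbfb in Treg. With an FDR of at most 0.001 the Foxp3 shares were 82.7, 72.9, 19.8, 85.4, 84.2, 93.6 and 93.3%, the common shares 12.2 and 35.3% and the co-occupancy 5.80, 2.00 and 5.45%. With all deposited positions the Foxp3 shares were 86.7, 92.4, 33.6, 93.5, 95.5, 98.3 and 98.2%, the common shares 15.4 and 14.6% and the co-occupancy 12.1, 5.09 and 5.05%. With the 10000 highest positions the Foxp3 shares were 54.4, 61.0, 11.1, 59.2, 70.9, 79.6 and 80.9%, the common shares 63.9 and 46.2% and the co-occupancy 28.5, 3.55 and 4.39%. With the 20000 highest the Foxp3 shares were 65.8, 71.8, 14.5, 81.2, 83.7, 87.7 and 92.2%, the common shares 48.3 and 36.3% and the co-occupancy 22.6, 3.12 and 3.66%. At 100 bp the Foxp3 shares were 80.5, 78.2, 25.3, 85.1, 85.8, 94.0 and 93.8%, the common shares 9.17 and 13.5% and the co-occupancy 4.43, 2.32 and 3.61%. At 500 bp the Foxp3 shares were 89.6, 87.4, 34.5, 91.9, 91.1, 97.9 and 96.3%, the common shares 15.1 and 24.0% and the co-occupancy 11.5, 8.60 and 11.1%. With each peak as its midpoint the Foxp3 shares were 80.5, 78.2, 25.3, 85.1, 85.8, 94.0 and 93.8%, the same by construction as at 100 bp. The moves of the Foxp3 shares follow from the construction, as shorter lists and distances leave fewer positions to find. The common shares and the co-occupancy of Elf1 with Ets1 were highest with 10000 positions; the cause was not tested. Ranked by fold enrichment, the highest 10% of positions had Foxp3 shares of 3.74, 6.01, 0.378, 13.1 and 14.6% for the 5 libraries in that order; the cause was not tested. A further 37 values moved likewise: shares in the reverse direction of each pair, and the backgrounds of the Foxp3 shares, each higher with peaks moved by 10 kb.

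The split of Foxp3 peaks by score or width was not run, as the list has no score and 1 width, and the alternatives for gene lists and motifs were not run. No paired analysis was possible because the Foxp3 list is pooled over its replicates and the input libraries that share their numbers were not analysed here. Depth is unknown, so how far it limits each list could not be assessed.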

Other observations

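The test of low fold enrichment, both tests of the chromosome X region, recurrence from Treg to CD4 and the count of Cbfb positions at the end were chosen after the results they bear on had been seen. Recurrence between cell types was higher at Foxp3 peaks than elsewhere, in both directions. Of the CD4 Elf1 positions in the top 10000 that lay at Foxp3 peaks, 74.8% recurred in the Treg top 10000, against a median of 65.1% (central 95% 63.3 to 67.1) in lists matched on score. From Treg to CD4 the shares were 80.6 and 71.1%. For Ets1, 67.9% of the CD4 positions at Foxp3 peaks recurred in Treg, against 52.1% (50.2 to 54.1), and 77.5% of the Treg positions recurred in CD4, against 53.5%.

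A first pattern to weigh is that CD4 lists of 10000 positions covered more Foxp3 peaks than Treg lists of that length, for Elf1 by 59.2 to 54.4% and for Ets1 by 70.9 to 61.0%. Lower Elf1 or Ets1 signal in Treg where Foxp3 binds had been expected to leave recurrence at Foxp3 peaks below the matched lists, and a weaker Treg library overall to leave it inside their range. Recurrence was above them, at 74.8% for Elf1 and 67.9% for Ets1, but it was raised in both directions, so sites that recur in any library could hide either effect and the test decides neither. Relative to matched positions, the fold ratio of Ets1 at Foxp3 peaks was -0.098, below the matched range. On the same measure Elf1 went from -0.13 to 0.094 with the list used. Both explanations therefore stay open for both factors. Depth and immunoprecipitation yield cannot be told apart from cell type with 1 library per group.

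A second pattern is the low Foxp3 share of the strongest Treg Elf1 positions, 14.6% at ranks 1 to 500 against 24.8% at ranks 1001 to 2000. Whether a higher limit of fold enrichment would move the share was not tested, and the median fold of the 10000 highest Treg Elf1 positions was 13.2. Positions under 4-fold were too few to be the reason: they were only 4 of the 500, and without them the share was 14.7% (11.7 to 18.1). Nor did the strongest positions lack Ets1, which was present at 42.4 and 42.0% of the 2 rank groups; among positions with Ets1 the shares were 24.5% (18.9 to 30.9) and 40.7% (36.0 to 45.6). CD4 Elf1 gave 15.2% (12.2 to 18.7) and 20% (17.6 to 22.6), with overlapping intervals, but 16.8% (13.4 to 20.6) and 27.0% (23.7 to 30.5) among positions with Ets1. Whether the strongest Elf1 positions lie at another class of site, such as promoters, was not tested, because no gene annotation on this build was used here.

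The third pattern is the region of extreme enrichment on chromosome X. A hypothesis is DNA added outside the immunoprecipitation, such as cloned DNA carried into a library, since the 5 Cbfb positions over 20-fold went with 4 in CD4 Elf1, a library of another factor and cell type. The test was set to need a density found nowhere else, and a second stretch 13298 bp away held 6 such Cbfb positions, while CD4 Elf1 windows elsewhere held up to 5; since 1 length of DNA could cover both stretches, added DNA and binding cannot be told apart. Low coverage of a control shared by all libraries would raise the fold in each, and only 2 of the 5 libraries had a position over 20-fold in the first stretch. But 4 had one in the second, and Treg Ets1 had 22.0-fold at 7154921, just outside its limits, so this explanation stays open. Controls that differed between libraries stay open, as the control is not given in the sources used here. No biological explanation was tested.

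Of the 39 Cbfb positions with the highest lower bounds outside that region, 8 had a Treg Elf1, 8 a CD4 Elf1, 9 a Treg Ets1 and 10 a CD4 Ets1 position of the top 10000 within 200 bp. These were larger shares than in the Cbfb top 10000, where the same 4 lists had a position at 3.47, 3.85, 4.34 and 4.76%.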
